A study of Mus musculus with 12 samples.

How the data were processed

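RNA from sorted mouse prostate epithelial cells was purified with a column kit, amplified and labelled with the NuGEN Ovation V2 system and hybridized to arrays, per the labels. The deposited values are log2 signals per probe set; the submitters' processing notes name RMA and oligo with no version, parameters or order. RMA ordinarily includes background correction, quantile normalization of probes and a summary per probe set. All deposited values lay between 0.695 and 14.3 with none missing and array medians between 3.76 and 3.99, so they were used as log2 values without further normalization. The scale could not be set against scanner files, which were not used here, and no detection p was used. The number of arrays limits the precision.

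The table held 41345 probe sets. Of these, 23521 had a single gene symbol, 1814 had several and 16010 were not in the annotation. The 23521 covered 22180 genes; where a gene had several probe sets, as 1082 did, the brightest was kept. Entrez identifiers of 23328 probe sets matched a mouse reference gene table, which changed 0 symbols. Positions were not used here. Genes were tested when at least 2 arrays lay above the lower quartile of the table (2.98), which left 20135. Probe sets without a single symbol were examined apart, in the closing section.

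Each of the 12 samples was assigned to 1 of 6 groups (3 gates, LY6D+ or LY6D-) from its label. Models were fitted with limma 3.58.1 in R 4.3.3, with a mean per group, default empirical Bayes moderation (6 residual and 3.28 prior degrees of freedom) and Benjamini-Hochberg adjustment over genes within a contrast, at a threshold of 0.05. The contrasts were LY6D+ against LY6D- within each gate and over the 3 gates, the differences of these between gates, the gates against each other (mean of the LY6D+ and LY6D- groups), and LY6D+ luminal against LY6D+ basal cells. SE values are moderated standard errors. The mouse number pairs the LY6D+ and LY6D- libraries of a gate. After removing the group means the paired libraries correlated at 0.0220 in the luminal, 0.149 in the Sca1-high and 0.407 in the basal gate, and libraries of mouse 5 across gates at a median of 0.0355 (highest 0.414). Arrays of a gate and mouse correlated at a median of 0.863, against 0.843 for arrays of a group. Mouse was left out of the main model as planned, not because of these values, and was used as a fixed block and a random block (consensus correlation 0.150) in alternatives. No 2 arrays were identical (highest r 0.913).

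Of 27 gene lists fixed before the data were examined, 25 were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Adjustment was over lists within a contrast. The lists were basal epithelial, luminal epithelial, prostate secretory proteins, proximal luminal progenitor, urothelial, squamous differentiation, stem and progenitor factors, cell cycle, lymphoid, myeloid, endothelial, fibroblasts, smooth muscle, seminal vesicle, neuroendocrine, immediate early and heat shock, interferon response, antigen presentation, Notch, Wnt, endoplasmic reticulum and unfolded protein response, cholesterol synthesis, mucosal defence and ribosomal proteins. Erythroid (1 member tested) and mitochondrially encoded genes (0 members) fell under the minimum of 5 members, a minimum chosen after the data were seen. Lists overlap in places: 4 of 16 luminal epithelial, 5 of 19 secretory and 1 of 18 basal epithelial members stand in another list, and 0 of the endothelial members do. Where median, mean and test of a called list differed in sign, that is stated. Of the 487 genes in the 27 lists, 63 were not tested. For 39 the annotation gave no probe set, among them all 13 mitochondrially encoded genes, 19 had only probe sets of several symbols, among them Krt5, and 5 fell under the filter. The tested lists short of the most members were mucosal defence and ribosomal proteins (5 each) and lymphoid, interferon response and cholesterol synthesis (4 each). Of the sort genes, Ly6a had no probe set in the annotation. Some genes and 1 of the lists are not reported here. With an estimated correlation the calls that held were secretory and myeloid genes for basal against luminal and secretory and luminal epithelial genes for Sca1-high against luminal. Exact permutation tests of list means per library, chosen after the data were seen, were two-sided: relabelling 4 against 4 libraries, or flipping the sign of 6 mouse pairs. They treat libraries, or pairs, of a mouse as independent, which they are not.

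The genes named were set by a rule: the sort genes; per contrast the 10 largest rises and 10 largest falls among genes past the threshold whose libraries did not overlap between gates, or that moved the same way in every mouse pair; where fewer than 5 passed, the 5 with the smallest p each way; and per list up to 4 members past the threshold or, where none passed and the list is discussed, the 2 with the largest change. Unnamed loci, microRNA and snoRNA genes and receptor segments were passed over. Krt15 in the luminal gate, Ptprc and Pecam1 in single libraries, and Krt8 and Krt18 in the library that stood apart were chosen after their values were seen.

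Detection was tested on simulated data with the spread of these arrays, 20135 genes and 50 changed genes per size. For 2 libraries against 2, the model called 4% of changes of 1 on the log2 scale, 48% of 2, 94% of 3 and 86% of 4, with 6 false calls. For 4 against 4 it called 12%, 78%, 98% and 100%, with 8 false calls. The genes and libraries simulated for these counts were independent, without the shared mice or the libraries that stood apart in the real data. Detection and false calls on the real arrays may therefore differ from these. For an unshifted list of 16 genes sharing a correlation of 0.25, the unadjusted camera p was counted in 100 simulated sets. It was under 0.05 in 36% of them at the preset correlation and in 5% with an estimated correlation. These shares are for a list tested alone, without the adjustment over lists that calls rest on.

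Alternatives changed 1 choice at a time: mouse as a fixed block or a random block, no filter, a stricter filter (2 arrays above the table median of 3.905, 15775 genes), arrays centred on their medians, a repeated quantile normalization, empirical Bayes with trend and robust options, array weights, only the groups compared, the mean of a gene's probe sets, an added threshold of 1 on the log2 scale, an estimated inter-gene correlation, and each library left out in turn. Chosen after the data were seen were leaving out both Sca1-high libraries of mouse 5, exchanging their LY6D labels, and leaving out the 3 libraries of mouse 5 that lay apart on the first principal component (both basal and luminal LY6D-).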

Results

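Gene expression was measured on 12 arrays of RNA from prostate epithelial cells of wild-type, hormone-naïve male mice. The cells lacked the lineage markers CD45 (immune cells), CD31 (endothelial cells) and Ter119 (erythroid cells) and were sorted into 3 gates: luminal (low Sca1, low CD49f), Sca1-high (CD49f-positive) and basal (intermediate Sca1, CD49f-positive). Each gate was divided by the surface protein LY6D, giving 6 groups of 2 mice. The luminal libraries came from mice 4 and 5, the Sca1-high libraries from mice 1 and 5, and the basal libraries from mice 3 and 5, so that mouse 5 gave libraries of every group. Values are on the log2 scale. Gate values below are means ± SD over 4 libraries of 2 mice (n = 4), group values means ± SD (n = 2) and differences log2 ± SE. The main fits and list tests treat libraries of a mouse as independent, which they are not. The SD, SE and p of gate comparisons therefore do not measure the spread between mice. The small number of arrays limits the precision. Arrays of a group correlated across genes at a Pearson r between 0.806 and 0.878 (median 0.843), against a median of 0.839 for arrays of another gate and another mouse. Genes are not independent replicates.

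The transcripts of the sort proteins gave a mixed picture. Ly6d signal was 5.01 ± 0.27 in LY6D+ and 4.86 ± 0.35 in LY6D- luminal cells, 5.95 ± 0.02 and 5.44 ± 0.83 in basal cells, and 5.12 ± 0.59 and 6.17 ± 1.71 in Sca1-high cells, and no LY6D comparison passed the test for it (adjusted p = 1.00 in each gate, limma). Among Sca1-high libraries of mouse 5, Ly6d was 4.70 in the library labelled LY6D+ and 7.37 in the library labelled LY6D-. Itga6, which encodes CD49f, was 6.49 ± 0.48 in the luminal, 6.99 ± 0.76 in the Sca1-high and 8.47 ± 0.80 in the basal gate, a basal minus luminal difference of 1.98 ± 0.46 that missed the threshold (adjusted p = 0.150). Ptprc, which encodes CD45, was 6.46 ± 2.02 in the luminal gate, with 8.90 in LY6D- cells of mouse 5, against 3.42 ± 0.24 in the basal gate (adjusted p = 0.149). Pecam1, which encodes CD31, was 8.43 ± 1.22 in the Sca1-high, 7.42 ± 1.30 in the basal and 5.18 ± 0.58 in the luminal gate. Ly6a, which encodes Sca1, had no probe set of its own and was not analysed here.

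In the first 2 principal components the luminal libraries stood apart on the second, at 32.5 to 69.8, while the other 8 libraries were negative. These components carried 25.2% and 18.7% of the variance. On the first, 3 libraries of mouse 5 lay apart: basal LY6D+ at 71.5, basal LY6D- at 73.1 and luminal LY6D- at 32.9, with the other 9 at 18.5 or less. The same 3 had the fewest genes above the lower quartile of the table (18009, 17859 and 17585, against 18536 or more). The Sca1-high library of mouse 5 labelled LY6D+ stood apart in another way: its median r with the other arrays was 0.799, the lowest of the 12. Its signals for the luminal keratins Krt8 and Krt18 were 6.48 and 5.30, while the other 11 libraries lay at 8.45 or more for Krt8 and 10.02 or more for Krt18.

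**Figure D1:**
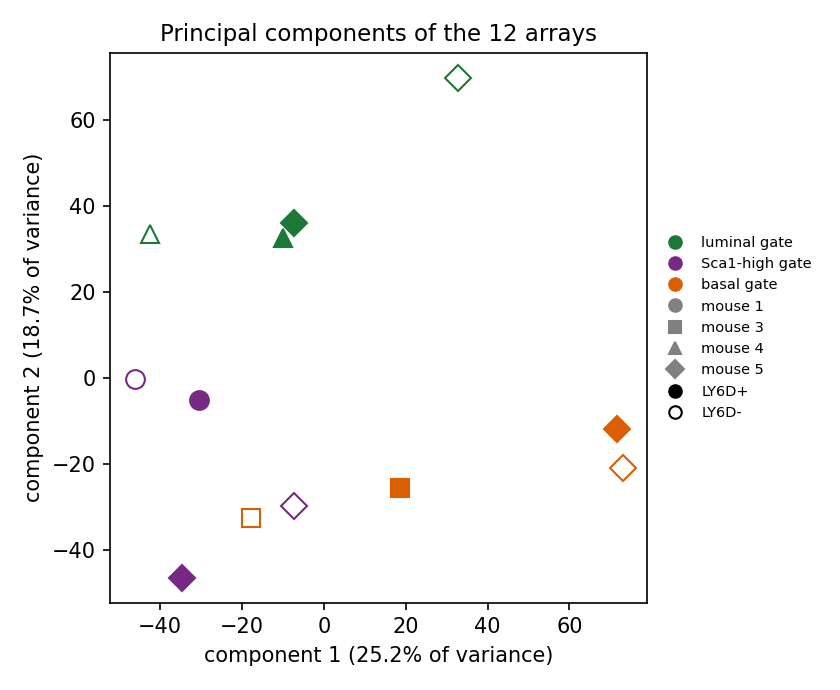
Principal components of the 12 arrays over the tested genes, with component 1 (25.2% of variance) on the x axis and component 2 (18.7%) on the y axis; colour marks the gate, marker shape the mouse, and filled or open symbols LY6D+ or LY6D-. Luminal libraries lie between 32.5 and 69.8 on component 2 and the other 8 below 0.

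Basal cells were compared with luminal cells to describe the 2 epithelial compartments that the gates were drawn to separate. With limma, 84 of 20135 genes passed an adjusted p of 0.05, 28 higher and 56 lower in the basal gate. The largest fall was in Mxi1, which encodes a MAX partner that opposes MYC: 11.21 ± 0.61 in luminal and 4.61 ± 0.41 in basal cells, a difference of -6.60 ± 0.40 (adjusted p = 7.5e-04). Basal cells were higher for the protocadherin Pcdh7, at 6.14 ± 0.44 against 3.03 ± 0.23 (3.11 ± 0.27, adjusted p = 0.00400, with the luminal signal near the lower quartile of the table, 2.98), and for the gap junction protein Gja1, at 9.07 ± 0.30 against 6.02 ± 0.44. Other genes higher in basal cells were Pdk4, a kinase that restrains pyruvate oxidation (4.46 ± 0.60), Fgfbp1, a carrier of fibroblast growth factors (3.96 ± 0.60), Plaur, the urokinase receptor (3.31 ± 0.55), the heme exporter Flvcr1 (3.19 ± 0.33), Sema6a (3.15 ± 0.50), Net1 (2.81 ± 0.43) and Plscr1 (2.73 ± 0.42). Also lower in basal cells were the secreted ribonuclease Rnase1 (-4.79 ± 0.64), Cdcp3 (-4.56 ± 0.55), the beta-defensin Defb42 (-4.53 ± 0.43), the chemokines Ccl4 (-4.36 ± 0.57) and Cxcl3 (-4.08 ± 0.65), the co-stimulatory molecule Cd86 (-4.18 ± 0.35), Glb1l3 (-4.05 ± 0.51) and Ms4a5 (-3.99 ± 0.63). Calls of Mxi1, Pcdh7, Defb42, Cd86 and Azgp1 held without any single library and under every alternative but 1, given with the count below, and each other named call ended under further ones.

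Grouped by list, 17 of 18 basal epithelial genes were on the higher side in basal cells (mean difference 1.59, adjusted p = 3.9e-15, camera), a call that was lost at an adjusted p = 0.0528 with an estimated correlation. In this list 1 gene passed over all genes and 11 when adjusted over the list alone. The gene that passed was Col17a1, a hemidesmosome collagen, at 7.58 ± 0.70 against 5.44 ± 0.61. Squamous differentiation genes were higher (mean 0.84, 17 of 21 positive, adjusted p = 8.5e-06, 0.134 as the adjusted p with an estimated correlation), with Krt16, a keratin of activated squamous epithelium, at 9.02 ± 0.57 against 5.27 ± 1.75. Probes for Krt14, Krt15, Krt16 and Krt17 can cross-react among related keratins, which was not tested here. Endothelial genes (mean 0.95, 15 of 16 positive) and cholesterol synthesis genes (mean 0.54, 11 of 16 positive) were also called higher, at adjusted p = 5.1e-06 and 0.00393, and at adjusted p = 0.167 and 0.209 with an estimated correlation. The endothelial difference came from LY6D- basal cells, with a list mean of 6.38 against 4.43 in LY6D+ basal and 4.46 in all luminal cells. No endothelial gene passed over all genes; Emcn differed by 2.68 ± 0.66 (adjusted p = 0.171), with the same division of the basal gate.

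Prostate secretory protein genes were lower in basal cells (mean -2.19, 2 of 19 members positive, adjusted p = 7.2e-19, 0.0404 as the adjusted p with an estimated correlation). Of these, 4 passed over all genes and 15 when adjusted over the list alone. They were the zinc-binding glycoprotein Azgp1 (8.02 ± 0.52 in luminal, 4.70 ± 0.50 in basal cells), the peptidase Mme (9.08 ± 0.91 and 5.94 ± 0.76), the apolipoprotein Apof (7.17 ± 0.37 and 4.26 ± 1.09) and Gdpd1 (6.05 ± 1.37 and 4.20 ± 0.21). Myeloid genes were lower as well (mean -2.14, 0 of 18 positive, adjusted p = 1.3e-21, 0.0404 as the adjusted p with an estimated correlation), 5 past the threshold over all genes and 15 when adjusted over the list alone. Luminal signal for these was high: the macrophage proteins Cd68 and Adgre1 were at 10.45 ± 0.06 and 7.62 ± 1.36, the mannose receptor Mrc1 at 5.81 ± 0.87 and the lysosomal protease Ctss at 8.35 ± 0.90. In basal cells the same 4 genes were at 6.20 ± 0.72, 4.26 ± 0.53, 3.27 ± 0.24 and 6.04 ± 0.55. Antigen presentation genes fell with them (mean -1.02, 1 of 15 positive, adjusted p = 3.9e-07, 0.0894 as the adjusted p with an estimated correlation), led by the class II genes H2-Aa (9.54 ± 0.50 against 6.26 ± 0.21) and H2-Eb1 (7.85 ± 1.06 against 4.63 ± 0.25). These myeloid and class II signals, like the luminal Ptprc signal given above, came from cells sorted as CD45-negative. Ptprc is itself a member of the myeloid list.

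Other lists called lower in basal cells were seminal vesicle (mean -2.68), endoplasmic reticulum and unfolded protein response (-0.76), luminal epithelial (-0.49), lymphoid (-0.38) and interferon response (-0.34), with adjusted p between 1.7e-08 and 0.0198. With an estimated correlation their adjusted p lay between 0.0867 and 0.339. The peptidase Dpp4 of the luminal list passed over all genes (5.59 ± 0.72 in luminal, 3.38 ± 0.26 in basal cells). Calls of lymphoid, interferon response and cholesterol synthesis ended without at least 1 library each: without luminal LY6D+ mouse 4, luminal LY6D- mouse 5 or basal LY6D- mouse 5 for lymphoid genes, without luminal LY6D+ or LY6D- mouse 5, basal LY6D+ mouse 3 or basal LY6D- mouse 5 for interferon genes, and without luminal LY6D- mouse 4 or basal LY6D- mouse 5 for cholesterol genes. Without luminal LY6D- mouse 5 the means were -0.24 for lymphoid, -0.14 for interferon response and -0.49 for endoplasmic reticulum genes, the last still called. The interferon mean was -0.54 without luminal LY6D- mouse 4, and the cholesterol mean 0.30 without basal LY6D- mouse 5. Lymphoid (-0.10) and interferon calls (-0.08) also ended without the 3 libraries of mouse 5 apart on component 1, and the cholesterol mean was 0.35, still called. Not called were proximal luminal progenitor, urothelial, stem and progenitor factors, cell cycle (median -0.07, mean 0.02), fibroblasts, smooth muscle, neuroendocrine, immediate early and heat shock, Notch, Wnt, mucosal defence and ribosomal proteins, at adjusted p between 0.0686 and 0.810. Single members of uncalled lists passed: Upk1a, a urothelial plaque protein, at 9.35 ± 0.17 in luminal and 5.39 ± 0.76 in basal cells, and Lgr4, an R-spondin receptor, at 4.38 ± 0.28 and 5.71 ± 0.43. An exact permutation test of the list means, 4 libraries against 4 and two-sided, gave its smallest possible p of 0.0286 for 8 of 25 lists, an adjusted p of 0.0893.

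The basal against luminal count depended on single libraries. It was 255 without luminal LY6D- mouse 4 (28 higher, 227 lower) and 187 without basal LY6D- mouse 3 (138 higher, 49 lower). It was 47 and 23 without luminal LY6D+ mouse 4 and mouse 5, 15 and 41 without basal LY6D+ mouse 3 and mouse 5, and 21 without basal LY6D- mouse 5. With mouse as a fixed block it was 100, with 53 higher and 47 lower, of which 26 were among the 84, a comparison that then rests on mouse 5. With arrays centred on their medians it was 31. Without the 3 libraries of mouse 5 apart on component 1 it was 0, with differences of -6.08 for Mxi1 (adjusted p = 0.0673), -3.41 for Azgp1 (0.0858), 2.62 for Pcdh7 (0.0951), -4.35 for Defb42 (0.0951) and -3.95 for Cd86 (0.116). Fewer libraries estimate the spread there.

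**Figure D2:**
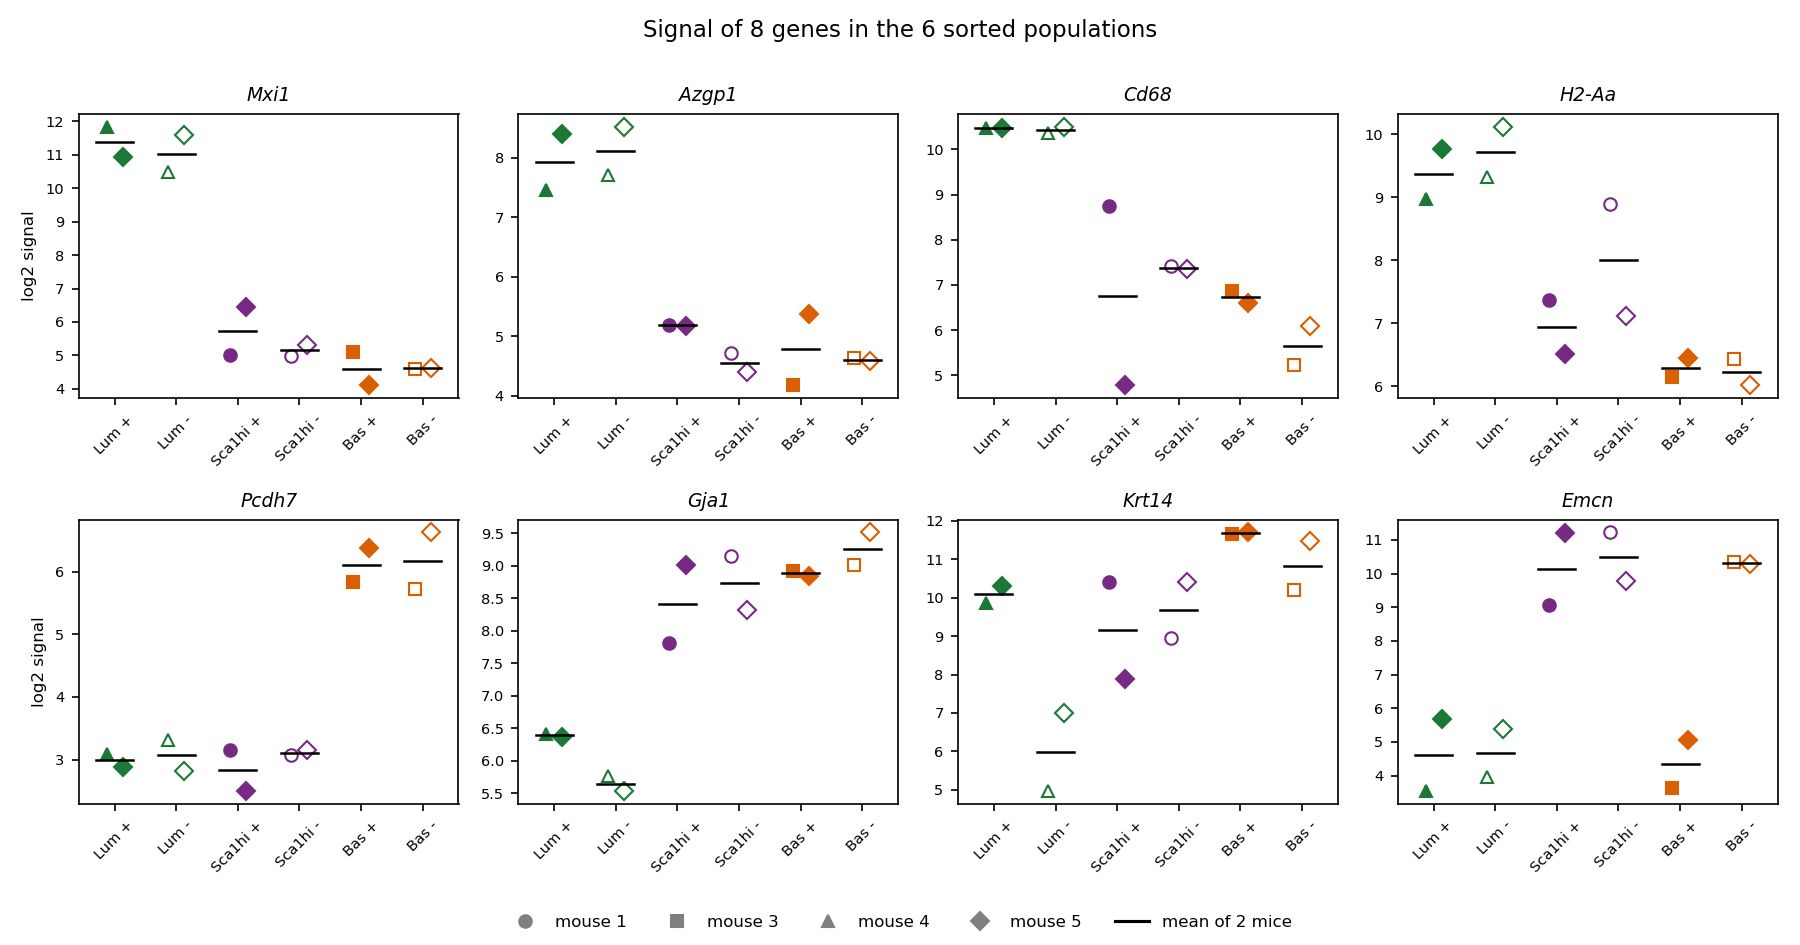
Log2 signal (y axis) of Mxi1, Azgp1, Cd68, H2-Aa, Pcdh7, Gja1, Krt14 and Emcn in each of the 12 libraries, by group (x axis); filled symbols are LY6D+, open symbols LY6D-, marker shape is the mouse, colour the gate and the bar the group mean. Mxi1 is at 11.21 ± 0.61 (SD, n = 4 libraries of 2 mice) in the luminal gate and 4.61 ± 0.41 in the basal gate. Emcn is at 4.34 ± 1.01 (SD, n = 2) in LY6D+ and 10.31 ± 0.05 in LY6D- basal cells.

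Sca1-high cells were set against luminal cells to ask how this CD49f-positive gate differs from the luminal compartment. Lower in Sca1-high cells were Mxi1 (5.44 ± 0.69, a difference of -5.77 ± 0.40, adjusted p = 0.00243), Defb42 (-4.45 ± 0.43), Upk1a (-4.32 ± 0.43), Cd86 (-3.78 ± 0.35) and Azgp1 (-3.15 ± 0.32). The 4 luminal libraries are those of the basal comparison too, so calls in both are not independent. In all, 28 genes passed, 8 higher and 20 lower in Sca1-high cells. The 8 genes with higher signal included Emcn, an endothelial sialomucin (10.33 ± 1.07 against 4.64 ± 1.05, adjusted p = 0.0203), Adgrl4, an endothelial adhesion receptor (5.14 ± 0.74), the fatty acid carrier Fabp4 (4.86 ± 0.62), Ctla2a (3.51 ± 0.49), the matrix protein Efemp1 (2.86 ± 0.40), S100a13 (2.80 ± 0.33), Tiparp (2.61 ± 0.35) and Gja1 (2.55 ± 0.30). Lower were also Glb1l3 (-4.37 ± 0.51), the beta-defensin Defb1 (-4.03 ± 0.53), Mme (-3.39 ± 0.50), Elapor1 (-3.32 ± 0.40), the tetraspanin Tspan1 (-3.19 ± 0.26) and Gdpd1 (-1.79 ± 0.23). The calls of Mxi1, Defb42, Cd86 and Tspan1 held without any single library and under every alternative but 1, given with the count below, and the other named calls did not.

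By list, 14 of 25 were called in this comparison. Endothelial genes were higher (mean 1.62, 15 of 16 positive, adjusted p = 9.4e-09, camera), a call lost at an adjusted p = 0.0981 with an estimated correlation. In this list 1 member passed over all genes and 9 did when adjusted over the list alone. Pecam1, itself a member of the list, was on the higher side, by 3.25 ± 0.58 (adjusted p = 0.113, limma). Basal epithelial genes were higher too (mean 0.64, 14 of 18 positive, adjusted p = 0.00691), and this call ended with mouse as a block (mean 0.43) and without luminal LY6D- mouse 4, Sca1-high LY6D+ mouse 1 or Sca1-high LY6D- mouse 5. The latter was also lost at an adjusted p = 0.320 with an estimated correlation. Secretory protein genes (mean -1.76, 2 of 19 positive) and luminal epithelial genes (mean -0.75, 1 of 16 positive) were lower, each at an adjusted p of 0.0427 with an estimated correlation. Also called lower were seminal vesicle (mean -2.29), myeloid (-1.21), endoplasmic reticulum and unfolded protein response (-0.93), antigen presentation (-0.63), ribosomal proteins (-0.54), immediate early and heat shock (-0.51), mucosal defence (-0.49, with a median of 6.2e-04 on the other side of 0), interferon response (-0.29) and stem and progenitor factors (-0.25). Their adjusted p lay between 5.4e-12 and 0.0326, and between 0.0781 and 0.221 with an estimated correlation. The stem and progenitor call ended without luminal LY6D+ or LY6D- mouse 5 and without Sca1-high LY6D+ or LY6D- mouse 1, and the interferon call without luminal LY6D- mouse 5 or Sca1-high LY6D+ mouse 1. Without luminal LY6D- mouse 5 their means were -0.16 and -0.09, and the interferon mean was -0.49 without luminal LY6D- mouse 4. The library that stood apart, Sca1-high LY6D+ mouse 5, had the lowest list means for ribosomal (7.26) and immediate early genes (7.90), and without it the differences were -0.30 and -0.32. Without both Sca1-high libraries of mouse 5 they were -0.17 and -0.21, antigen presentation was at -0.37 and myeloid at -0.79, all 4 still called. Calls of mucosal defence (-0.42, adjusted p = 0.0583), stem and progenitor (-0.16) and interferon genes (-0.09) ended without the 3 libraries of mouse 5 apart on component 1. Exact permutation tests of list means gave the smallest possible p of 0.0286 for 9 of 25 lists (two-sided, adjusted p = 0.0794).

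Removing libraries moved the count of 28 as well. It was 165 without luminal LY6D- mouse 4, 88 without Sca1-high LY6D+ mouse 1, 17 without Sca1-high LY6D+ mouse 5, 15 without Sca1-high LY6D- mouse 1, and 13 without any of luminal LY6D+ mouse 5, basal LY6D- mouse 3 and basal LY6D- mouse 5, left out in turn. With mouse as a fixed block it was 104, 5 higher and 99 lower, with 15 shared, which again rests on mouse 5, and with medians centred it was 17, 3 higher and 14 lower. With only the groups compared it was 13, all lower, so that every higher call, among them Emcn, Adgrl4 and Fabp4, was lost. Without the 3 libraries of mouse 5 apart on component 1 it was 0, with -5.49 for Mxi1 (adjusted p = 0.0579), -3.01 for Tspan1 (0.0526), -4.11 for Defb42 (0.0845) and -3.83 for Cd86 (0.0919).

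Between the CD49f-positive gates, 2 genes passed, both lower in Sca1-high than in basal cells. The mitochondrial aldehyde dehydrogenase Aldh2 was at 7.47 ± 0.45 against 10.83 ± 0.30 (-3.36 ± 0.20, adjusted p = 7.2e-04, limma). Pcdh7 was at 2.97 ± 0.31 against 6.14 ± 0.44 (-3.17 ± 0.27, adjusted p = 0.00673, limma). The Sca1-high signal of Pcdh7 lay under the lower quartile of the table (2.98), which leaves the size of its difference uncertain. The Aldh2 call ended when a gene's probe sets were averaged (-1.99), and the Pcdh7 call when only the groups compared were fitted (adjusted p = 0.0986) and without both Sca1-high libraries of mouse 5 (0.0532) or the 3 libraries of mouse 5 apart on component 1 (0.140), where 3 genes passed, 1 of them shared. Genes with the smallest p that did not pass were Serping1 (3.22 ± 0.54), Hspa1b (1.33 ± 0.22), Ctla2a (2.86 ± 0.49), Rgs5 (3.63 ± 0.63) and Cryab (2.53 ± 0.45), each at an adjusted p of 0.166, and Wipi2 (-2.07 ± 0.24), Lonrf1 (-2.29 ± 0.29) and Ptpn23 (-1.68 ± 0.22), at adjusted p of 0.0743 and 0.0887. Krt16 of the squamous list differed by -2.98 ± 0.53 and did not pass either (adjusted p = 0.166). Of the 25 lists 7 were called, all lost with an estimated correlation (adjusted p of 0.326 or more). Myeloid genes were higher in Sca1-high cells (mean 0.93, 18 of 18 positive). Basal epithelial (-0.96), ribosomal (-0.63), cholesterol synthesis (-0.51), squamous (-0.51), immediate early and heat shock (-0.39) and stem and progenitor genes (-0.38) were lower. The immediate early call ended without any of Sca1-high LY6D+ mouse 5, Sca1-high LY6D- mouse 5, basal LY6D+ mouse 3 and basal LY6D- mouse 5. The stem and progenitor call ended without Sca1-high LY6D+ mouse 1, basal LY6D+ mouse 5 or basal LY6D- mouse 5, the cholesterol call without basal LY6D- mouse 5, and the squamous call with mouse as a block (mean -0.59). Without basal LY6D- mouse 5 the means were -0.26 for immediate early, -0.24 for stem and progenitor and -0.27 for cholesterol genes. Without Sca1-high LY6D+ mouse 1 they were 0.57 for myeloid and -0.59 for immediate early genes, both called. Without Sca1-high LY6D+ mouse 5, which stood apart, they were -0.38 for ribosomal genes, still called, and -0.19 for immediate early genes. Without both Sca1-high libraries of mouse 5 they were -0.25, still called, and -0.09, where the immediate early call ended. Without the 3 libraries of mouse 5 apart on component 1 the means were -0.57 for basal epithelial and -0.38 for ribosomal genes, both called, and the stem and progenitor (-0.16), immediate early (-0.28) and cholesterol calls (-0.18) ended. List calls numbered 11 without basal LY6D+ mouse 5. The median difference of all genes was 0.11 here and -0.02 with medians centred. With mouse as a fixed block the gene count was 80, all lower in Sca1-high cells, a comparison that then rests on mouse 5. It was 133 without basal LY6D- mouse 3, 30 without Sca1-high LY6D+ mouse 1, 13 without Sca1-high LY6D- mouse 5, 5 without Sca1-high LY6D+ mouse 5 and 4 without Sca1-high LY6D- mouse 1.

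LY6D+ and LY6D- cells of the luminal gate were compared to describe the cells that LY6D marks within this gate. The basal epithelial list was higher in LY6D+ cells, with 16 of 18 members positive (mean 1.06, median 0.37, adjusted p = 6.9e-05), a call lost at an adjusted p = 0.436 with an estimated correlation. The list mean differed by 1.02 in mouse 4 and 1.09 in mouse 5. Its keratins Krt14, Krt15 and Krt17 had differences of 4.11 ± 0.90, 3.31 ± 1.02 and 3.62 ± 0.89. Krt14 was 10.09 ± 0.32 in LY6D+ and 5.98 ± 1.42 in LY6D- luminal cells, against 11.25 ± 0.71 in the basal gate. No member passed over all genes and 2 did when adjusted over the list alone. Also called higher were luminal epithelial (mean 0.46, adjusted p = 0.00942) and squamous genes (mean 0.45, adjusted p = 0.00962), both at adjusted p = 0.436 with an estimated correlation, with the claudin Cldn8 at 2.39 ± 0.52 and Krt16 at 2.73 ± 0.75. Called lower were antigen presentation (mean -0.39, 2 of 15 positive), smooth muscle (-0.44, 3 of 13 positive) and lymphoid genes (-0.55, 5 of 14 positive), at adjusted p between 0.00962 and 0.0376, and at adjusted p = 0.436 with an estimated correlation. Among lymphoid members the granzyme Gzma differed by -3.31 ± 0.86, and among the others Myh11, smooth muscle myosin, by -1.37 ± 0.25 and H2-Eb1 by -1.38 ± 0.56; none of these passed over all genes.

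No single gene passed in the luminal LY6D comparison with limma, and 716 had an unadjusted p under 0.05 where 1006.8 were expected by chance. The smallest adjusted p, 0.0727, belonged to the lymphocyte chemokine Xcl1 (9.72 ± 1.38 in LY6D- and 4.39 ± 0.01 in LY6D+ cells). Other genes with the smallest p were Me2 (-2.59 ± 0.31), Gdpd1 (-2.29 ± 0.32), Spink11 (-1.61 ± 0.25) and Fam174a (-1.57 ± 0.27) on the lower side, and Fam136a (3.85 ± 0.54), Zfp429 (2.42 ± 0.44), the interferon gene Ifnb1 (1.75 ± 0.35), the claudin Cldn3 (1.15 ± 0.23) and Treml4 (1.43 ± 0.30) on the higher side, none past the threshold. The count was 70 without luminal LY6D- mouse 4, 7 without luminal LY6D+ mouse 4, and 2 without either of luminal LY6D+ mouse 5 and luminal LY6D- mouse 5. It was 1 with mouse as a random block and 0 with mouse as a fixed block. Lists called numbered 12 without luminal LY6D- mouse 4 and 3 without luminal LY6D+ mouse 4 or luminal LY6D- mouse 5, libraries whose absence ended the squamous, smooth muscle and antigen presentation calls. The luminal epithelial call ended without luminal LY6D- mouse 4, and the lymphoid call with mouse as a block and without luminal LY6D+ mouse 5, luminal LY6D- mouse 5, basal LY6D- mouse 3, basal LY6D- mouse 5 or both Sca1-high libraries of mouse 5 (adjusted p = 0.0537). Without luminal LY6D- mouse 5 the means were 0.69 for luminal epithelial, 0.28 for squamous, -0.26 for lymphoid and -0.25 for antigen presentation genes, and without luminal LY6D- mouse 4 they were 0.23 for luminal epithelial and -0.84 for lymphoid genes. Without the 3 libraries of mouse 5 apart on component 1 the gene count was 1, and of the lists only basal and luminal epithelial stayed called.

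In the basal gate, LY6D+ cells had lower endothelial signal than LY6D- cells. The 16 endothelial genes had a mean difference of -1.95 and a median of -1.48 with 0 positive (adjusted p = 5.0e-21), a call lost at an adjusted p = 0.0855 with an estimated correlation. List means differed by -2.07 in mouse 3 and -1.83 in mouse 5. Emcn was 4.34 ± 1.01 in LY6D+ and 10.31 ± 0.05 in LY6D- cells (-5.97 ± 0.93, adjusted p = 0.435), and the endothelial cadherin Cdh5 differed by -4.48 ± 1.30. No member passed over all genes and 7 did when adjusted over the list alone. Pecam1, itself a member of the list, was 6.44 ± 1.05 in LY6D+ and 8.40 ± 0.30 in LY6D- basal cells, which had been sorted as CD31-negative. Seminal vesicle genes were called higher in LY6D+ cells (mean 1.47, 11 of 12 positive, adjusted p = 3.3e-04), a call lost at an adjusted p = 0.857 with an estimated correlation, with Svs6 at 4.04 ± 1.37. The call also ended without basal LY6D+ mouse 5 (mean -0.11) and without basal LY6D- mouse 3 (0.51), while the mean was 3.05 without basal LY6D+ mouse 3 and 2.44 without basal LY6D- mouse 5. It ended also without the 3 libraries of mouse 5 apart on component 1 (0.86, adjusted p = 0.0756). Interferon response genes were called lower (mean -0.37, 3 of 16 positive, adjusted p = 0.00318), with Gbp3 at -1.18 ± 0.49, a call that ended without basal LY6D+ or LY6D- mouse 3 and at an adjusted p = 0.857 with an estimated correlation.

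Over all genes of the basal gate, 2 passed, both higher in LY6D+ cells: the small RNA genes Mir1191 (8.35 ± 0.42 against 5.21 ± 0.17) and Snora33 (9.01 ± 0.77 against 4.98 ± 0.33), each at an adjusted p of 0.0435. They lie outside the rule for named genes and were named after their values were seen. With quantile normalization, trend and robust options, array weights, only the groups compared or the mean of probe sets, each of these calls ended. The Snora33 call also ended without both Sca1-high libraries of mouse 5. Both calls ended with mouse as a fixed block and without the 3 libraries of mouse 5 apart on component 1, where the count was 0, and both ended without any of luminal LY6D+ or LY6D- of mouse 4 or 5, Sca1-high LY6D- of mouse 1 or 5, basal LY6D+ of mouse 3 or 5, and basal LY6D- mouse 5, left out in turn. Without basal LY6D- mouse 3 the count was 1, another gene. Genes that did not pass included Clca3a2 (2.92 ± 0.44), Fbxw5 (1.69 ± 0.35), the interferon-inducible Ifi204 (-5.08 ± 0.78), the protease Adamts4 (-2.40 ± 0.41), Sparcl1 (-5.01 ± 0.92) and Ctla2a (-3.75 ± 0.69). List calls numbered 8 without basal LY6D- mouse 5 and 5 without any of Sca1-high LY6D+ mouse 1, Sca1-high LY6D+ mouse 5 and basal LY6D+ mouse 3.

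In the Sca1-high gate, 0 genes and 0 lists passed with limma and camera, and 486 genes had an unadjusted p under 0.05. Ly6d ran against the labels in mouse 5 (4.70 in the library labelled LY6D+, 7.37 in that labelled LY6D-); without this pair 4 lists were called, 7 with its labels exchanged, and 1 without the 3 libraries of mouse 5 apart on component 1. Genes with the smallest p were Spinkl (5.25 ± 1.33 in LY6D+ and 11.74 ± 0.17 in LY6D- cells), Serp1 (-2.77 ± 0.40), Gmfb (-2.95 ± 0.48), Pdcd10 (-2.93 ± 0.50) and Gnpnat1 (-5.11 ± 0.93) on the lower side, and Gap43 (2.10 ± 0.35), Ccnyl1 (2.29 ± 0.48), the efflux pump Abcb1a (2.08 ± 0.49), Zxda (1.67 ± 0.40) and Uprt (2.17 ± 0.55) on the higher side, at adjusted p of 0.916 or more. Endothelial list means differed by -1.21 in mouse 1 and 1.07 in mouse 5. The gene count was 17 without Sca1-high LY6D+ mouse 1 and 3 without Sca1-high LY6D+ mouse 5, and 0 with mouse as a block. Lists called numbered 8 without Sca1-high LY6D+ mouse 1, 3 without Sca1-high LY6D- mouse 5 and 1 without basal LY6D+ mouse 3 or mouse 5.

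Over the 3 gates together, 0 genes passed for LY6D with limma and 528 had an unadjusted p under 0.05. The genes with the smallest p were the cytoskeletal scaffold Tacc1 (-1.11 ± 0.19), the small heat shock protein Cryab (-2.13 ± 0.37), Xcl1 (-1.77 ± 0.32), Adamts4 (-1.20 ± 0.24) and the matrix protein Sparc (-1.01 ± 0.20), with Gap43 (0.85 ± 0.20), Fam136a (1.29 ± 0.31), Clca3a2 (0.97 ± 0.26), Smarce1 (0.86 ± 0.23) and Serpini1 (0.49 ± 0.13) on the higher side. Lists called were endothelial (mean -0.67), antigen presentation (-0.26) and secretory protein genes (-0.33) on the lower side and basal epithelial genes (0.36) on the higher side, at adjusted p between 9.3e-07 and 0.0383, all at 0.604 with an estimated correlation. With the LY6D labels of the Sca1-high libraries of mouse 5 exchanged, 12 lists were called and the secretory call ended (mean -0.14, adjusted p = 0.163). The endothelial mean was then -1.03 and the basal epithelial mean 0.55, against -1.05 and 0.55 without both libraries. The secretory (-0.32, adjusted p = 0.0793) and antigen presentation calls (-0.24, 0.0713) ended without the 3 libraries of mouse 5 apart on component 1. Antigen presentation list means were lower in LY6D+ cells in 6 of 6 mouse pairs (exact sign-flip permutation p = 0.0313, two-sided, adjusted p = 0.608). Mouse 5 gave 3 of these pairs, and with signs flipped by mouse (4 mice) the exact p was 0.125, the smallest possible. The difference was only -0.0051 in basal cells of mouse 5. It was -0.11 in Sca1-high cells of mouse 5, where it would turn if the labels were exchanged. The gene count was 2 without luminal LY6D+ mouse 5 or Sca1-high LY6D+ mouse 5. List calls numbered 9 without Sca1-high LY6D+ mouse 5, 8 without luminal LY6D- mouse 4, 7 without basal LY6D- mouse 5, and 1 without luminal LY6D- mouse 5 or Sca1-high LY6D- mouse 1, where the antigen presentation call ended (mean -0.14 without the latter). The basal epithelial call ended with mouse as a block (adjusted p = 0.0592), without a filter (0.0526) and without any of luminal LY6D+ mouse 5, luminal LY6D- of mouse 4 or 5, Sca1-high LY6D+ mouse 1, Sca1-high LY6D- mouse 1, basal LY6D+ mouse 5 and basal LY6D- mouse 3. Its mean was 0.23 without Sca1-high LY6D+ mouse 1, 0.18 without basal LY6D- mouse 3 and 0.54 without basal LY6D- mouse 5. The secretory call ended without any of luminal LY6D+ mouse 4, luminal LY6D- mouse 5, Sca1-high LY6D+ mouse 5, Sca1-high LY6D- mouse 1 (mean -0.20), basal LY6D+ mouse 3 (-0.09) and basal LY6D- mouse 5 (-0.18), and its mean was -0.56 without basal LY6D+ mouse 5.

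**Figure D3:**
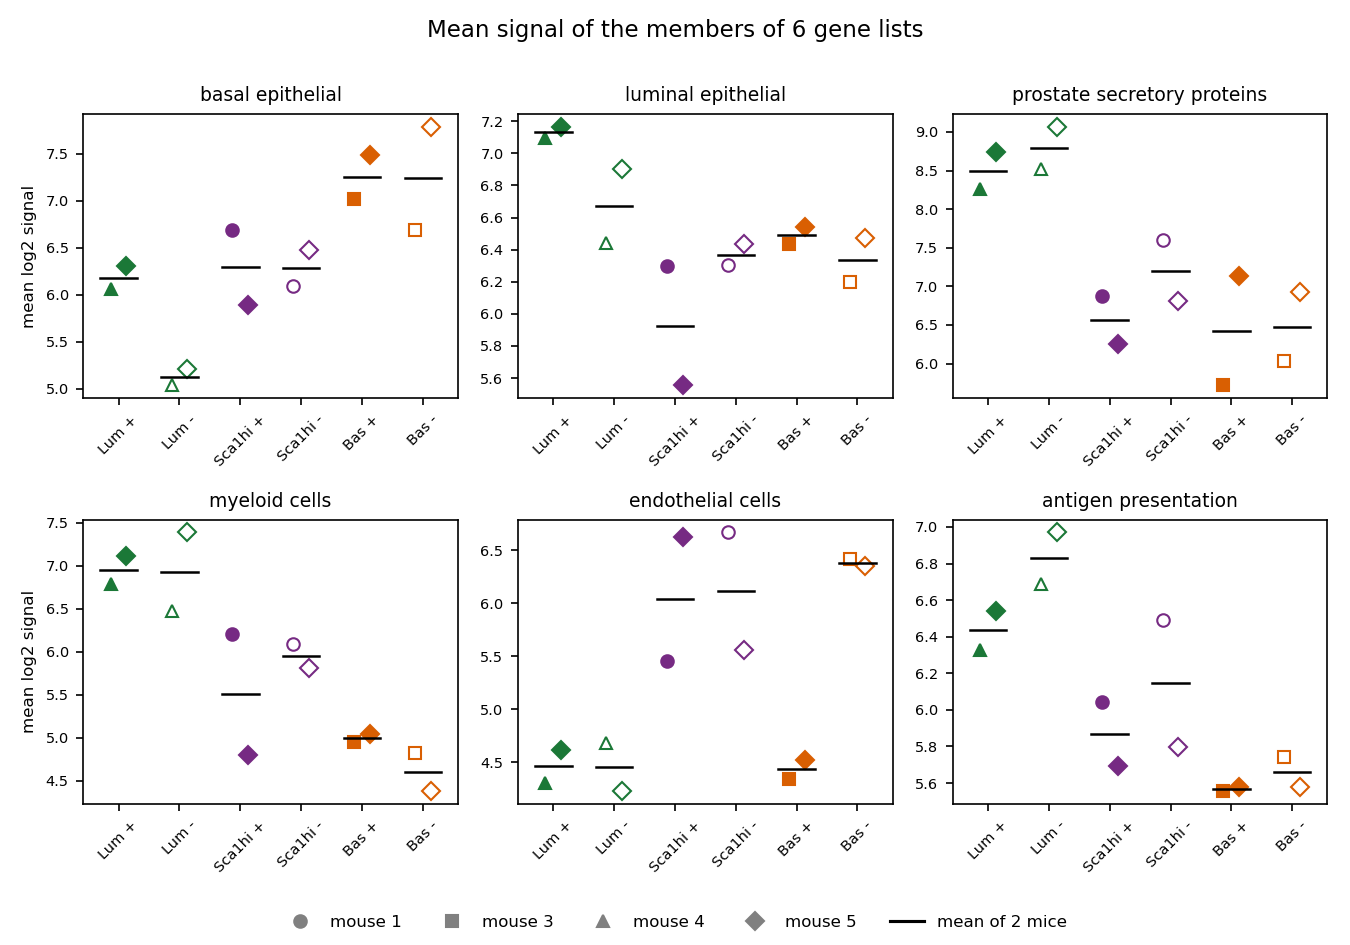
Mean log2 signal (y axis) of 6 gene lists in each of the 12 libraries, by group (x axis), with filled symbols for LY6D+, open symbols for LY6D-, marker shape for the mouse, colour for the gate and a bar for the group mean. The basal epithelial mean is 6.18 ± 0.17 (SD, n = 2) in LY6D+ and 5.13 ± 0.12 in LY6D- luminal cells.

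LY6D+ cells of the luminal and basal gates were then set against each other. Here 6 genes passed, 3 on each side. Higher in the luminal cells were Mxi1 (6.77 ± 0.57, adjusted p = 0.0129), Defb42 (5.32 ± 0.61, adjusted p = 0.0414) and Ifnb1 (3.23 ± 0.35, adjusted p = 0.0335), the last at 5.50 ± 0.79 against 2.26 ± 0.06, a value under the lower quartile of the table (2.98), so that the size of its difference is uncertain. Lower were Pcdh7 (-3.12 ± 0.38, adjusted p = 0.0499), Snora33 (-4.07 ± 0.42) and Mir1191 (-2.71 ± 0.32), the last 2 named after their values were seen. The Pcdh7 call ended without a filter (adjusted p = 0.0508), with the stricter filter, with medians centred (0.0918), with only the groups compared (0.0880), with the mean of probe sets and without both Sca1-high libraries of mouse 5. The Defb42 call ended with medians centred (0.0918) and without both Sca1-high libraries of mouse 5 (0.0715), and the Ifnb1 call without both of them (0.0694). The count was 0 with only the groups compared and without the 3 libraries of mouse 5 apart on component 1. By list 12 were called, none of them with an estimated correlation, where the smallest adjusted p was 0.0640. Called higher in luminal cells were secretory (mean 2.07, 18 of 19 positive), seminal vesicle (1.96), myeloid (1.95, 18 of 18 positive), antigen presentation (0.87), luminal epithelial (0.64), endoplasmic reticulum and unfolded protein response (0.55), neuroendocrine (0.40) and interferon response genes (0.39). Basal epithelial (-1.07, 2 of 18 positive), squamous (-0.69), cholesterol synthesis (-0.58) and ribosomal genes (-0.27) were called lower. The myeloid gene Adgre1 differed by 3.96 ± 0.80 and the secretory gene Msmb by 4.98 ± 1.32, neither past the threshold over all genes. With mouse as a fixed block the count was 37, with 4 shared, where the part between the gates rests on mouse 5, with quantile normalization it was 4, 3 higher and 1 lower, and with the block the seminal vesicle call ended (mean 0.75). The gene count was 15 without luminal LY6D+ mouse 4, 10 without Sca1-high LY6D+ of mouse 1 or 5, 1 without basal LY6D+ mouse 5 or basal LY6D- of mouse 3 or 5, and 0 without basal LY6D+ mouse 3 or Sca1-high LY6D- of mouse 1 or 5. List calls also ended when libraries were left out in turn: squamous without luminal LY6D+ mouse 5, seminal vesicle and endoplasmic reticulum without basal LY6D+ mouse 3, and interferon response without either of these. Neuroendocrine and ribosomal calls ended without luminal LY6D+ mouse 4, luminal LY6D- of mouse 4 or 5, or basal LY6D+ mouse 5, and the cholesterol call without luminal LY6D+ of mouse 4 or 5 or basal LY6D+ mouse 5. The ribosomal call also ended with the labels of the Sca1-high libraries of mouse 5 exchanged (adjusted p = 0.0526). Without basal LY6D+ mouse 3 the secretory mean was 1.37 and the seminal vesicle mean 0.38, and without basal LY6D+ mouse 5 the seminal vesicle mean was 3.54 and the neuroendocrine mean 0.25. The ribosomal mean was -0.09 without luminal LY6D+ mouse 4 and -0.45 without luminal LY6D+ mouse 5. Neuroendocrine (0.25), cholesterol (-0.40) and ribosomal calls (-0.19) ended without the 3 libraries of mouse 5 apart on component 1 too.

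No gene passed when the LY6D difference of a gate was tested against that of another, with limma: 494 genes for luminal against basal, 587 for luminal against Sca1-high and 475 for Sca1-high against basal had an unadjusted p under 0.05. Left out in turn, luminal LY6D- mouse 4, luminal LY6D- mouse 5, luminal LY6D+ mouse 5 and basal LY6D- mouse 3 gave 11, 2, 1 and 1 genes for luminal against basal. For luminal against Sca1-high, 7 passed without luminal LY6D- mouse 4, 2 without luminal LY6D- mouse 5 or Sca1-high LY6D+ mouse 1, and 1 without luminal LY6D+ mouse 5 or Sca1-high LY6D+ mouse 5. For Sca1-high against basal, 14 passed without Sca1-high LY6D+ mouse 1 and 1 without basal LY6D- mouse 3. Across 20135 genes, LY6D differences correlated between gates at a Pearson r of 0.0587 (Spearman rho 0.0534) for luminal and basal, 0.00244 (-0.00963) for luminal and Sca1-high, and -0.0630 (-0.0329) for Sca1-high and basal. Without mouse 5 these Pearson values were 0.117, 0.109 and 0.0980. The luminal LY6D difference was also set against the basal minus luminal difference with no array on both sides, to ask whether LY6D+ luminal cells differed in the direction of basal cells across genes. The mean r was 0.0527 (0.0486 and 0.0567 for the 2 ways of dividing the mice), and 0.00374 (-0.0586 and 0.0661) with Sca1-high in place of basal cells. These 5 correlations are across genes, which are not independent replicates, and carry no p.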

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

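The patterns weighed here, the correlation of endothelial genes outside the basal gate, the tests of the gene lists as a measure of exchanged labels and of few epithelial cells, the count at an unadjusted p in the splits of LY6D, and the check of 28 basal genes were chosen after the results were seen. The remaining tests had their predictions written first. Of these, the correlation of endothelial genes over 12 libraries, the share of basal-high genes, the median difference of all genes and the splits of the gates were judged to decide less after their values were seen. So was the correlation across genes as a measure of exchanged labels. Gene lists whose LY6D difference was called different between a pair of gates were singled out because the difference of differences passed with camera, although none did with an estimated correlation. For luminal against basal these were basal epithelial (mean 1.04, adjusted p = 6.1e-04, 0.607 with an estimated correlation), endothelial (1.96, 2.8e-12, 0.298) and seminal vesicle (-1.44, 0.0296, 0.721). For luminal against Sca1-high they were basal epithelial (1.05, 0.00359, 0.584), luminal epithelial (0.90, 0.00193, 0.380), squamous (0.59, 0.0197, 0.612), smooth muscle (-0.53, 0.0142, 0.520) and interferon response (-0.49, 0.0142, 0.584). For Sca1-high against basal they were myeloid (-0.85, 0.0394, 0.718), endothelial (1.88, 2.5e-11, 0.354), seminal vesicle (-2.17, 5.1e-04, 0.718), interferon response (0.58, 5.9e-04, 0.715) and ribosomal proteins (-0.66, 0.0439, 0.718). Without both Sca1-high libraries of mouse 5, all 5 calls of luminal against Sca1-high ended, with means of 0.46 for basal epithelial, 0.46 for luminal epithelial, 0.16 for squamous, -0.36 for smooth muscle and -0.22 for interferon response genes. Those of Sca1-high against basal then ended for myeloid (-0.28), seminal vesicle (-0.44), interferon response (0.31) and ribosomal genes (-0.43), while endothelial genes stayed called at 0.74. With the labels of these libraries exchanged the same 9 calls ended, as did seminal vesicle for luminal against basal (adjusted p = 0.0565), and endothelial genes for Sca1-high against basal were at 0.81. For luminal against basal the basal epithelial mean was 1.59 without basal LY6D- mouse 3 and 0.50 without basal LY6D- mouse 5, where the call ended. Without Sca1-high LY6D+ mouse 5 alone, calls of luminal against Sca1-high ended for basal epithelial (0.65), luminal epithelial (0.53), squamous (0.33), smooth muscle (-0.47) and interferon response genes (-0.31), and those of Sca1-high against basal for myeloid (-0.14), seminal vesicle (-0.83) and ribosomal genes (-0.17). Without Sca1-high LY6D+ mouse 1 the last 3 were -1.55, -3.50 and -1.15, all called. The seminal vesicle mean for Sca1-high against basal was -0.59 without basal LY6D+ mouse 5 and -1.20 without basal LY6D- mouse 3. Without basal LY6D+ mouse 3 it was -3.75. The interferon mean for luminal against Sca1-high was -0.89 without luminal LY6D- mouse 4 and -0.09, not called, without luminal LY6D- mouse 5. Without the 3 libraries of mouse 5 apart on component 1, calls ended for basal epithelial (0.81) and seminal vesicle (-0.60) in luminal against basal, for squamous (0.42), smooth muscle (-0.42) and interferon response (-0.09) in luminal against Sca1-high, and for myeloid genes (-0.58) in Sca1-high against basal, where the ribosomal mean lay further from 0 and stayed called. Single libraries moved these numbers of called lists. For luminal against basal there were 10 without luminal LY6D- mouse 4 and 6 without basal LY6D- mouse 5. For luminal against Sca1-high there were 0 without Sca1-high LY6D+ mouse 5, 1 without Sca1-high LY6D- mouse 5, 2 without luminal LY6D+ mouse 4, 3 without luminal LY6D- mouse 5 and 10 without Sca1-high LY6D+ mouse 1. For Sca1-high against basal there were 2 without Sca1-high LY6D+ mouse 5 or basal LY6D+ mouse 5, 3 without luminal LY6D- of mouse 4 or 5 or Sca1-high LY6D- mouse 1, 8 without Sca1-high LY6D+ mouse 1 and 10 without basal LY6D- mouse 5. Probe sets without a single symbol were singled out as values outside the comparisons of genes. Of 13937 of them, 2 passed for LY6D in the Sca1-high gate (1 up, 1 down), 3 for basal against luminal (all up), 4 for Sca1-high against luminal (1 up, 3 down), 2 for Sca1-high against basal (both down) and 1 for LY6D+ luminal against LY6D+ basal (down).

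Endothelial genes were lower in LY6D+ than in LY6D- basal cells by a mean of 1.95 on the log2 scale in a sort that excluded CD31. Their median pairwise r was 0.540 over the 12 libraries, a value that includes the basal libraries where the pattern was seen, and 0.344 over the 8 other libraries with gate means removed, which leaves endothelial cells among the sorted cells open. The median difference of all genes was 0.0247, far from the list mean of -1.95, which argues against a uniform shift of the values used. The normalization named in the notes ordinarily holds that median near 0, so whether the arrays differed before normalization stays open. All 16 members were tested and 0 stand in another list, but 15 of 16 were also above the table median in the luminal gate, where Emcn was low, so a member above background does not by itself point to endothelial cells. Expression of these genes by the epithelial cells themselves stays open, as does whether LY6D enters at all, since the adjusted p was 0.0855 with an estimated correlation.

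The basal list was called higher in LY6D+ than in LY6D- luminal cells, with Krt14 at 10.09 against 11.67 in LY6D+ basal cells, but at an adjusted p of 0.436 with an estimated correlation and with 0 members past the threshold over all genes. Were basal cells carried into the sort, basal-high genes as a whole should follow; with arrays kept apart, 278 of 410 such genes were higher (67.8%, against 42.6% of all genes) in a first division of the mice, but 113 of 258 (43.8%, against 60.8% of all genes) in the other. Of the 28 genes called higher in basal cells, 19 were higher in LY6D+ luminal cells, 15 of them in both mice. By mouse, 20 were higher in mouse 4 and 19 in mouse 5, against 42.6% and 60.8% of all genes. These 28 were chosen with the same luminal libraries, so their count is not independent support and decides nothing. The share in the first division fell short of that predicted for carried basal cells. The 43.8% of the other met the prediction written first against them. Each division rests on the luminal libraries of 1 mouse and they differ. That prediction was therefore judged to decide less after the values were seen, and carried basal cells stay open. The median difference of all genes was 0.0168 against a list mean of 1.06, which argues against a uniform shift of the values used. Normalization ordinarily holds that median near 0, so whether the arrays differed before normalization stays open. A basal program in some luminal cells and no difference at all stay open too.

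Ly6d was 4.70 in the Sca1-high library of mouse 5 labelled LY6D+ and 7.37 in the library labelled LY6D-. A probe set near the floor is argued against by its place at percentile 83.8 of tested genes. Were the labels exchanged, the differences of mice 1 and 5 should oppose each other. Across genes r was -0.101, which met the prediction written first for an exchange. The -0.0779 of the luminal pair was set beside it after that value was seen. Across 25 lists r was -0.725, and -0.383 without endothelial and seminal vesicle genes, against 0.479 and 0.603 for the luminal mice. The mouse 5 difference was negative with every other pair across lists, from -0.108 to -0.824 (-0.383 to -0.536 without these lists). Few epithelial cells in the library labelled LY6D+ could give such opposition too, which leaves an exchange open. The library labelled LY6D+ had a luminal epithelial list mean of 5.56, with a gap of 0.645 to the next library where the largest SD in another group was 0.326. Few epithelial cells in it would give such a gap. The list holds Krt8 and Krt18, whose low signals in this library are given above, so the gap partly restates them. Both could hold, and nothing here decides between them. This library also had the lowest median r with the other arrays (0.799) and the lowest ribosomal list mean (7.26). Other explanations were not tested.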

How the results depend on the processing

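Of 60 named genes past the threshold, those that lost it numbered 30 with mouse as a block, 26 with medians centred, 29 with only the groups compared, 26 without both Sca1-high libraries of mouse 5, 59 without the basal and luminal LY6D- libraries of mouse 5, 11 with array weights, 10 with trend and robust options, 7 without a filter, 5 with quantile normalization, 5 with the mean of probe sets, 1 with the stricter filter and 0 with a random block. Of 71 called lists, 67 lost the call with an estimated correlation, 11 without both Sca1-high libraries of mouse 5, 12 with their labels exchanged (3 of them turned), 24 without the basal and luminal LY6D- libraries of mouse 5, 1 without a filter and 5 with mouse as a block, which ended no other list call of the report but added calls. Where a library left out leaves a group with 1, that library is assumed to vary like the others. Array weights are equal within a group by construction. Signal over background limits the weakly expressed genes. The cause of the changes below was not tested.

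Gene counts with mouse as a block were 0 for LY6D in basal cells, 104 for Sca1-high against luminal, 80 for Sca1-high against basal and 37 for LY6D+ luminal against LY6D+ basal; list counts were 1 for LY6D in Sca1-high cells and 11 for Sca1-high against basal. With a random block the luminal LY6D count was 1. With trend and robust options it was 2, with 0 for basal LY6D and 4 for Sca1-high against basal. With array weights the counts were 1 for luminal LY6D, 0 for basal LY6D and 28 for LY6D+ luminal against LY6D+ basal. Quantile normalization gave 0 for basal LY6D. Medians centred gave 31 for basal against luminal and 17 for Sca1-high against luminal. Only the groups compared gave 0 for basal LY6D, 13 for Sca1-high against luminal, 1 for Sca1-high against basal and 0 for LY6D+ luminal against LY6D+ basal. The mean of probe sets gave 0 for basal LY6D and 1 for Sca1-high against basal. With an estimated correlation lists called were 2 for basal against luminal, 2 for Sca1-high against luminal and 0 elsewhere.

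Without both Sca1-high libraries of mouse 5, gene counts were 5 for basal LY6D, 1 for LY6D over the gates, 10 for Sca1-high against basal and 10 for LY6D+ luminal against LY6D+ basal. List counts were 4 for LY6D in Sca1-high cells, 5 in basal cells and 9 over the gates, and 1 for the LY6D difference of luminal against Sca1-high and 1 for Sca1-high against basal. With their labels exchanged, gene counts were 7 for basal LY6D, 3 over the gates, 1 for the difference of luminal against basal, 133 for basal against luminal, 60 for Sca1-high against luminal and 8 for Sca1-high against basal. List counts were 7 for LY6D in Sca1-high cells, 12 over the gates, and 2 for the difference of luminal against Sca1-high and 2 for Sca1-high against basal. In the last, means turned to 0.17 for myeloid, 0.26 for seminal vesicle and -0.0709 for ribosomal genes, the latter by its test. Without the basal and luminal LY6D- libraries of mouse 5, gene counts were 1 for luminal LY6D, 0 for basal LY6D, 0 for basal against luminal, 0 for Sca1-high against luminal and 0 for LY6D+ luminal against LY6D+ basal, and list counts were 2 for luminal LY6D, 1 for Sca1-high LY6D, 2 over the gates and 3 for the difference of luminal against Sca1-high. Correlations of LY6D differences without mouse 5 were 0.109 for luminal with Sca1-high and 0.0980 for Sca1-high with basal. With luminal LY6D- libraries on both sides, those with the gate differences were 0.440 for basal and 0.521 for Sca1-high minus luminal, as sharing libraries raises them.

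With 1 library left out, gene counts ran from 15 to 255 for basal against luminal, 13 to 165 for Sca1-high against luminal, 2 to 133 for Sca1-high against basal, 0 to 15 for LY6D+ luminal against LY6D+ basal, and for LY6D from 0 to 70 in luminal, 0 to 17 in Sca1-high, 0 to 3 in basal cells and 0 to 2 over the gates. Differences of LY6D between gates ran from 0 to 11 for luminal against basal, 0 to 7 for luminal against Sca1-high and 0 to 14 for Sca1-high against basal. List counts ran from 10 to 15, 11 to 17, 6 to 11 and 9 to 13 for the first 4 comparisons, 3 to 12, 0 to 8, 3 to 8 and 1 to 9 for LY6D, and 2 to 10, 0 to 10 and 2 to 10 for the differences between gates. The seminal vesicle mean ran from -0.11 to 3.05 for LY6D in basal cells and from -3.02 to 0.14 for its difference between luminal and basal cells. The ribosomal mean ran from -1.15 to -0.17 for the difference of Sca1-high against basal, with a turned test at -0.25.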

Other observations

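All tested Notch (16 of 16) and immediate early and heat shock genes (21 of 21) lay above the table median in every gate. So did 12 of 12 members of the seminal vesicle list, a count that is thus not particular to them. Their list mean was lower in basal (-2.68) and Sca1-high cells (-2.29) than in luminal cells, and between LY6D+ and LY6D- cells it differed by 1.03 in Sca1-high cells of mouse 1, -2.43 in those of mouse 5, 0.86 in basal cells of mouse 3 and 2.09 in those of mouse 5. Proximal luminal progenitor genes, called in no comparison, differed by 0.76 in Sca1-high cells of mouse 1 and -0.94 in those of mouse 5. Myeloid genes lay above the table median for 18 of 18 members in the luminal, 17 in the Sca1-high and 13 in the basal gate.

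Chance groupings of the libraries were counted to see whether chance can be excluded. For LY6D over the gates, 90 of 100 splits had at least the real 528 genes at an unadjusted p under 0.05, with a highest of 3551, and 62 of 100 splits had at least the real 4 lists (highest 13), so chance cannot be excluded for either. Among the 30 splits that part every mouse pair, 21 had as many genes, with a highest of 865; the highest of 3551 came from a split that did not, which points to structure among the samples. The gate splits were fitted on the 8 libraries of the gates compared, with a mean per side and without the LY6D groups. Their real gene counts are therefore not those of the main model. For basal against luminal, 1 of 35 splits reached the real 104 genes, the real split itself (highest other 4), but 3 of 35 reached the real 12 lists (highest other 12). For Sca1-high against luminal, 1 of 35 reached the real 23 genes (highest other 2) and 1 of 35 the real 14 lists (highest other 13). For Sca1-high against basal, 2 of 35 reached the real 5 genes (highest other 6) and 7 of 35 the real 7 lists (highest other 10), so chance cannot be excluded there. The libraries of a gate come from 2 mice and mouse 5 is in every gate, so these 35 splits take as exchangeable libraries that are not. By mouse only 3 splits are possible, too few to exclude chance for any gate comparison.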
